A study of Homo sapiens with 6 samples.

How the data were processed

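RNA from HEK293A cells was profiled by sequencing in 6 libraries, 3 from cells given small interfering RNAs against UBE2A and UBE2B and 3 from cells given vehicle without siRNA. HEK293 is a line derived from human embryonic kidney, and HEK293A is one of its derivatives. Per the labels' protocols, cells were seeded at 10000 per cm2 in 60 mm dishes in medium with 10% serum and 1% antibiotics and grown for 18 to 24 h. They were then transfected with or without siRNA in 18.6 ul of a lipid reagent and harvested 48 h later; the labels give 25 uM of each siRNA and 50 uM in total. The control had vehicle and no siRNA, and its labels do not say whether the vehicle held the reagent, so a general response to siRNA moves with the knockdown here. The siRNA sequences, the density at harvest, the strand setting of the counting and the origin of replicates in separate cultures are not given in the sources used here. The p-values then measure only the spread between these libraries, which may be technical.

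The values came in 2 tables with both counts and FPKM per gene. The counts were deposited as whole reads per gene, unnormalized; the submitters' processing notes name HISAT2, HTSeq and hg38, with no versions. The deposited FPKM values equalled the count divided by gene length and by the library's total, as recomputed from the tables, and were not tested. The first table held 4 libraries and 19987 genes, with replicates 1 and 2 of each group. The second held 2 libraries and 19973 genes, with 1 control and 1 knockdown column that named the group and no replicate number. The tables shared 19922 genes, which were joined by Ensembl identifier. Of these, 17183 had the same coordinates and length in both tables and 2734 had a different length, so the gene models behind the counts differed between the tables. Symbols came from the reference name table for 19344 shared genes and from the deposited tables for 578.

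Total counted reads were 14564624 and 13537127 for control replicates 1 and 2 and 11306372 for the unnumbered control library. They were 13790963 and 13023190 for knockdown replicates 1 and 2 and 10887217 for the unnumbered knockdown library. A count of 3 reads was worth 0.206 to 0.276 CPM, the floor of each library, for counting error only. No pair of libraries agreed within sampling noise: the chi-square per gene, over genes with at least 20 reads in the pair, ran from 3.52 to 25.6, so none was treated as a duplicate.

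Changes between groups were tested with edgeR 4.0.16 in R 4.3.3 (TMM factors, the filterByExpr minimum, the quasi-likelihood test and Benjamini-Hochberg adjustment), with an adjusted p under 0.05 as the threshold. The design fixed before the data were examined had the group alone, over all 6 libraries and 13629 genes. The table of origin as a further term was 1 of the alternatives fixed at that time. Because the tables formed the strongest division among the libraries, values with this table term, and within each table, stand beside those of the fixed design. Both libraries of the second table have 1 partner only, so that table gives a difference and no test of its own. CPM values are per library with TMM factors, given as mean ± SD. The replicate numbers cover 2 pairs only, and were not taken as pairing the samples.

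The 28 gene lists, with 647 entries, were written before the data were examined and matched the tables in full. They were tested with camera in limma 3.58.1 on log2 CPM with a prior count of 2 and a preset inter-gene correlation of 0.01. Adjustment was over the 27 lists with at least 5 tested members. Named genes were UBE2A and UBE2B, and the 8 highest and 8 lowest log2 fold changes among genes past the threshold, with a mean of at least 5 CPM and no overlap between the groups. From each list the rule took the 2 members with the largest change past the threshold, or the 2 with the highest mean CPM where none passed. With no gene past the threshold in the fixed design, the rule was applied to the fit with the table term as well. The abundant list members that the rule took from the fixed design alone, none of them past its threshold, are in the counts and are not described singly. Of the genes the rule took, 3 are not reported here. Other genes are said to be chosen after their values were seen.

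The fits were tested on simulated data drawn on the real means and library sizes of the 13629 genes, with 50 genes changed at each of 4 folds. With the table term they recovered 62% of genes changed by 1.3-fold, 76% at 1.5-fold, 92% at 2-fold and 96% at 3-fold. Without it they recovered 4%, 22%, 62% and 88%. With no simulated change neither fit made a call. With the simulated changes 4.68% of the calls were false with the table term and 0% without it. The draws kept the difference between the tables and took their spread from the fit with the table term, so they favor that fit.

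Alternatives fixed beforehand were RLE factors, no filter beyond 1 count, a mean of at least 5 CPM, each library left out, a replicate block, the table term, the first table alone, DESeq2 1.42.0, limma-voom, a test against a 1.2-fold change, camera with an estimated correlation, and fry. The combinations of the table term with other choices, the test on genes with 1 model in both tables, the test on genes lacking certain 7-mers and the Gene Ontology terms were added after seeing the data. For the 7-mers, the longest 3′ UTR of at least 50 bases per gene was taken from the basic transcripts of GENCODE release 29, on the same genome build, for 11231 genes with a mean of at least 5 CPM, UBE2A and UBE2B left out. Each of 16213 7-mers found in at least 50 genes was scored by a z for the difference in mean log2 fold change between genes with and without it, after a fit on 3′ UTR length and GC content. The range of chance came from 100 permutations of the genes, and intervals of medians from bootstrap draws. These steps used Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1. Figures were drawn with matplotlib 3.10.9. The deposited tables held no fold changes of the authors' own that were used here.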

Results

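The study asked, from its title and design text, what UBE2A and UBE2B do in cells that sense mechanical signals and contact. UBE2A and UBE2B are the human RAD6 proteins, paralogous E2 enzymes that pass ubiquitin to histone H2B, to PCNA and to other substrates. Gene expression was read by RNA sequencing in HEK293A cells, an embryonic kidney line, 48 h after transfection. There were 3 libraries with siRNAs against both genes and 3 from cells given vehicle without siRNA. Each library held between 10887217 and 14564624 reads assigned to genes. Replicates 1 and 2 of each group came in 1 table, and a further control and knockdown library came in a second table without replicate numbers. Mitochondrial genes took 4.65% to 4.91% of the reads.

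UBE2A transcripts were lower in each knockdown library than in each control library. The CPM of UBE2A (ENSG00000077721, chromosome X, 119574536 to 119591083 on hg38, plus strand) was 99.6, 97.9 and 105 in the controls and 51.9, 57.7 and 49.1 in the knockdowns. The means were 101 ± 3.58 and 52.9 ± 4.38 (SD, n = 3), a log2 fold change of -0.93 (standard error 0.09 with the group as the sole term and 0.07 with the table of origin added), or a fall by 47.4%. UBE2B (ENSG00000119048, chromosome 5, 134371469 to 134392108, plus strand) showed a smaller difference: 63.1, 64.1 and 61.2 CPM in the controls and 51.9, 55.0 and 46.0 in the knockdowns. Its log2 fold change was -0.30 (standard errors 0.09 and 0.07), a fall by 18.8%. Both falls were partial, and the data hold no protein levels. With the group as the sole term, edgeR's adjusted p was 0.0668 for UBE2A and 1.00 for UBE2B. With the table of origin in the model the adjusted p was 1.64e-12 for UBE2A and 0.0127 for UBE2B. Within the tables the log2 fold changes were -0.85 and -1.09 for UBE2A and -0.25 and -0.41 for UBE2B, first table given first. The UBE2B call ended without control replicate 2 (adjusted p = 0.0757), without knockdown replicate 1 (0.103) and without the second table's control (0.183) or knockdown (0.190) library.

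**Figure D1:**
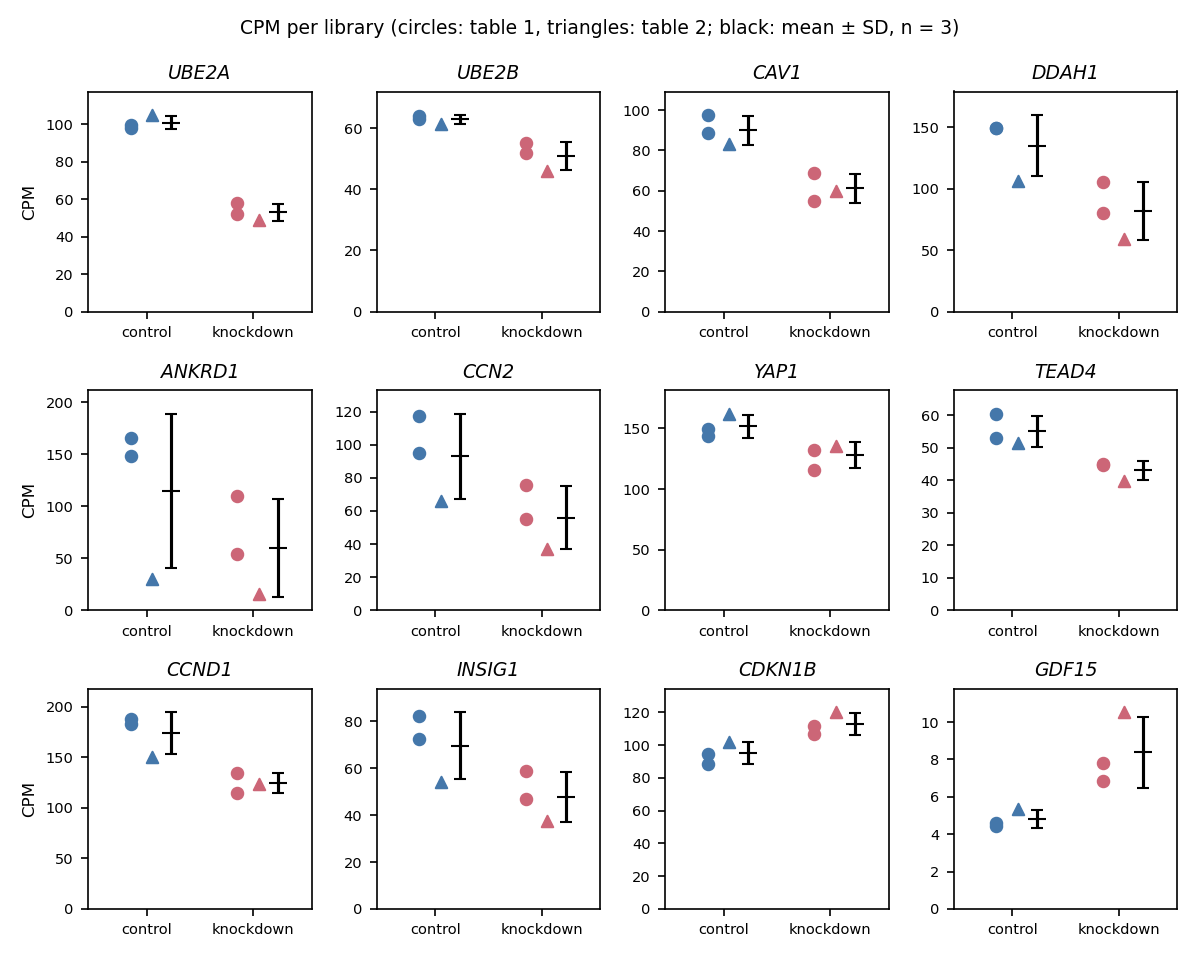
CPM of 12 named genes in the 6 libraries, control in blue and knockdown in red, with circles for the first table and triangles for the second; the black bars give the mean and SD of 3 libraries. UBE2A lay between 97.9 and 105 CPM in the controls and between 49.1 and 57.7 CPM in the knockdowns, and the levels of ANKRD1 differed more between the tables than between the groups.

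Apart from UBE2A, the lowest log2 fold changes among genes of at least 5 CPM with non-overlapping groups included that of DDAH1, which degrades asymmetric dimethylarginine (log2 fold change -0.73, from 135 to 81.7 CPM). B4GALT6, a lactosylceramide synthase (-0.62), LPCAT2, a lysophospholipid acyltransferase (-0.62), EMILIN2, an extracellular glycoprotein (-0.57), CAV1, the main protein of caveolae (-0.56), and the autophagy enzyme gene ATG10 (-0.55) followed. The highest rises were in H2BC21, a histone H2B gene (0.89, from 4.47 to 8.25 CPM), the stress cytokine GDF15 (0.79), the interferon-induced TRIM22 (0.70) and the major vault protein MVP (0.69). The transcription factor MAF (0.55), the lipid flippase ATP8A2, the pyruvate dehydrogenase kinase PDK4 and the acyltransferase MBOAT1 (0.47 for each of these last) came next. All these values are from the edgeR fit with the table term, in which each passed an adjusted p of 0.05; DDAH1 had an adjusted p of 2.00e-09 and H2BC21 of 0.00463. H2BC21 belongs to a family of near-identical genes, so its count is uncertain.

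With the group as the sole term, edgeR called 0 of 13629 genes, with 327 at an unadjusted p under 0.05. That share of the genes is below the 0.05 that p-values give where nothing changes. DESeq2 called 2, UBE2A among them, and limma-voom called 0. The libraries split by table along the first principal component, which held 56.1% of the variance. With the table as a term, 336 genes passed, 87 higher and 249 lower, with median log2 changes of 0.33 upward and 0.30 downward in size. Of the 336, 19 changed by at least 1.5-fold and 0 by at least 2-fold; 1917 genes had an unadjusted p under 0.05, and DESeq2 with the same term called 204. Among the 336, 122 had non-overlapping groups over the 6 libraries. Over all genes 7.70% had non-overlapping groups. The 10% that chance gives for 3 against 3 holds only for libraries with no other division. Each group here spans both tables, so that share cannot be set against it.

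**Figure D2:**
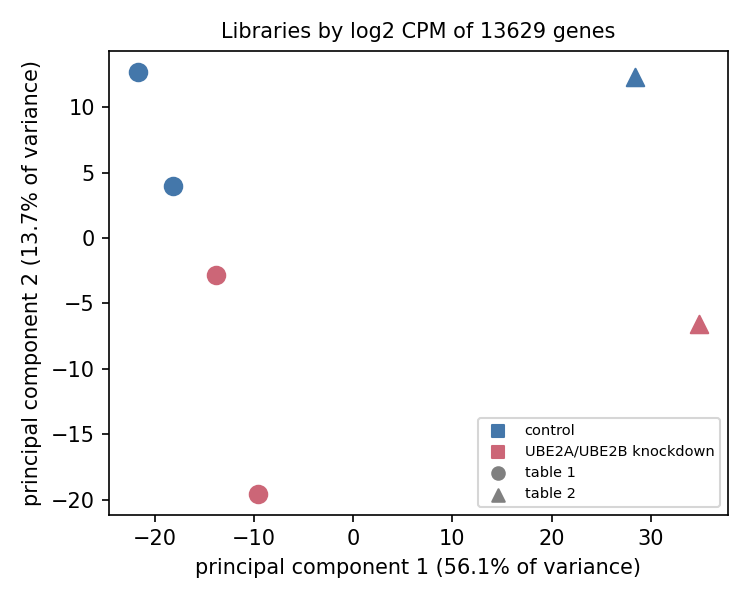
Principal components 1 and 2 of log2 CPM over 13629 genes, 1 point per library, with color for the group and shape for the table. Component 1, with 56.1% of the variance, separates the tables.

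The direction of the changes carried over to the libraries that took no part in calling them. In the first table alone 154 of 13672 genes passed, 24 higher and 130 lower. Of the 153 of these genes that could be followed, 146 (95.4%, exact 95% interval 90.8% to 98.1%) had the same sign in the second table's pair. That interval treats the genes as independent, although all were read in 1 pair. It does not measure how another pair would come out. The lower genes had a median log2 change of -0.38 in the first table and -0.29 in the second, and the higher genes 0.37 and 0.20. Over all genes 58.6% shared their sign, and Pearson's r across genes, which are not independent replicates, was 0.12. Of the 336 genes, 335 had the same sign in both tables; the other, RRP12, named after its values were seen, had -0.45 and 0.02. The count of 336 was 118 without control replicate 2, 98 without knockdown replicate 1, and 151 or 145 without the control or knockdown library of the second table.

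Target genes of YAP and TEAD, the transcriptional arm of the Hippo pathway that responds to cell contact and stiffness, were mostly lower after knockdown. The list did not pass with an estimated correlation. With the table term, 9 of 22 tested fell and 13 did not pass over all genes, and 1 rose and 9 fell when adjusted over the list alone. With the group alone 0 passed over all genes or over the list. Counts, log2 fold changes and medians of list members, here and below, are from the fit with the table term unless another is named. ANKRD1 had a log2 fold change of -0.95 (standard error 0.12, adjusted p = 1.68e-06) and CCN2, also known as CTGF, of -0.74 (0.08, adjusted p = 1.67e-07). The other members that fell, named after their values were seen, were CCN1, AMOTL2, AJUBA, CRIM1, FJX1, TGFB2 and MYOF. The second table held ANKRD1 at 15.8 CPM in its knockdown library, against 53.6 and 109 CPM in the first table's knockdowns, and the within-table log2 changes were -1.03 and -0.92. The list's median log2 fold change was -0.16, and camera gave an adjusted p of 0.0120 with the group alone and 0.00108 with the table term. With an estimated correlation the adjusted p was 0.610 and 0.674. With the group alone the call ended without control replicate 1 (0.151), control replicate 2 (0.0802), knockdown replicate 1 (0.0785) or the second table's knockdown library (0.119). Its median there was -0.10 without control replicate 1, -0.09 without control replicate 2 and -0.26 without knockdown replicate 2. With the table term the list passed in camera with each library left out (adjusted p from 5.15e-04 to 0.0131).

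Of 24 Hippo pathway components, 2 fell, the same as when adjusted over the list alone, and the list did not pass (camera adjusted p = 0.335 with the group alone, 0.293 with the table term). They were the TEAD family transcription factor gene TEAD4 (-0.35, adjusted p = 0.00481) and YAP1 itself (-0.24, adjusted p = 0.0120). The annotated 3′ UTR of YAP1 holds 2 copies of ATGAATTA, the 8-base sequence that goes with lower genes in these data, and that of TEAD4 holds none. Actin and SRF cytoskeleton genes had a median of -0.10, with 2 of 23 falling over all genes and 5 adjusted over the list alone. The actin crosslinker FLNA had -0.22 and TAGLN2 -0.19. Camera gave an adjusted p of 0.0120 with the group alone and 0.00613 with the table term (0.610 and 0.707 with an estimated correlation). The call with the table term ended without control replicate 1, at an adjusted p just above 0.05, and without knockdown replicate 1 (0.137). The call with the group alone ended without control replicate 1 (0.0972), control replicate 2 (0.0737) or knockdown replicate 1 (0.216). The median was -0.06 with the group alone without control replicate 1, and -0.05 with the table term without knockdown replicate 1.

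Matrix, adhesion and junction lists held few changed members. In the extracellular matrix list 2 of 25 fell, and 2 adjusted over the list alone: COL12A1 and THBS1, both at -0.56 (camera adjusted p = 0.156 with the group alone and 0.138 with the table term). Of 23 integrin and focal adhesion genes 1 fell, the integrin subunit gene ITGB1 (-0.18), and 3 adjusted over the list alone (0.198 and 0.169). With the group alone this list passed in camera without the second table's control library (adjusted p = 0.0236, median -0.08). Of 23 cell junction genes 0 passed over all genes and 4 were lower adjusted over the list alone (0.306 and 0.169); the catenin genes CTNNA1 and CTNNB1 had -0.05 and 0.02. Of 14 mechanosensor and nuclear envelope linker genes 0 passed either way (0.989 and 0.859), with -0.09 for LMNB2 and -0.12 for LMNB1.

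Cholesterol synthesis and uptake genes formed the list with the lowest camera p at the preset correlation. With the table term, 11 of 21 tested fell over all genes and 12 adjusted over the list alone. With the group alone 0 passed over all genes or over the list. In both fits 20 had a negative log2 fold change. INSIG1, a sterol-responsive regulator, had -0.55 (standard error 0.08, adjusted p = 1.22e-05), with within-table changes of -0.56 and -0.53. The list's median was -0.25; with the group alone it was -0.37 without knockdown replicate 2, and -0.37 or -0.16 without the second table's control or knockdown library. Camera gave an adjusted p of 5.27e-07 with the group alone and 4.02e-08 with the table term, and 0.610 and 0.674 with an estimated correlation. Of the Gene Ontology terms, tested after the data were seen, cholesterol biosynthetic process (24 genes) and sterol biosynthetic process (21 genes) did not pass with the table term (adjusted p = 0.142 each), with 6 genes lower and a median of -0.11 in each. Hypoxia and glycolysis genes had a median of -0.12, with 5 of 21 falling and 8 adjusted over the list alone. The glucose transporter genes SLC2A1 (-0.31) and SLC2A3 (-0.25) led them, and ENO1, LDHA and PFKP, named after their values were seen, also fell. Their camera adjusted p was 0.00484 with the group alone and 0.00108 with the table term (0.610 and 0.674 with an estimated correlation). That with the group alone ended without control replicate 2 (0.0565), knockdown replicate 1 (0.185) or the second table's control library (0.0519), with a median of -0.07 for the last. The median with the table term was -0.08 without control replicate 2. With that term the list passed in camera with each library left out (adjusted p from 5.23e-04 to 0.0271).

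**Figure D3:**
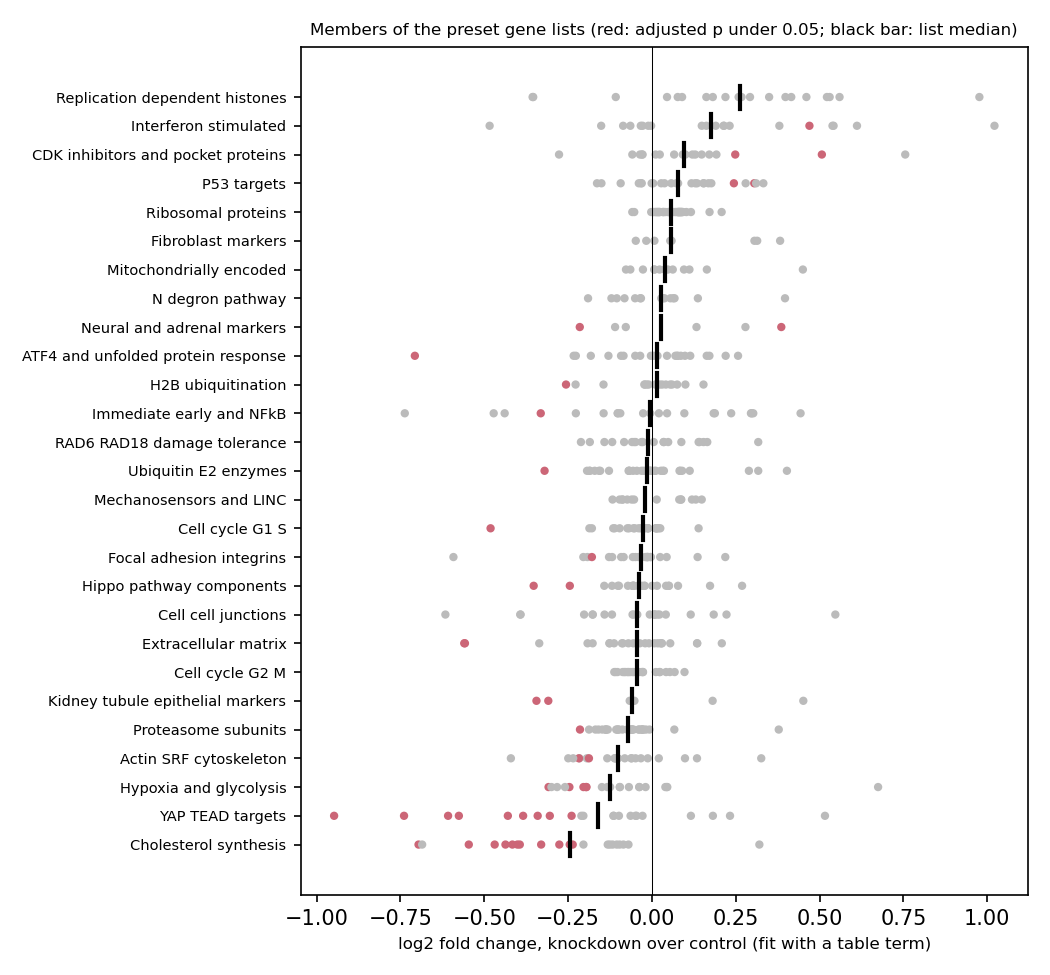
Log2 fold change of each tested member of the 27 gene lists in the fit with the table term, red where the adjusted p was under 0.05, with a black bar at each list's median. Cholesterol synthesis (median -0.25) and YAP/TEAD targets (-0.16) lie lowest, and histones (0.26) and interferon genes (0.18) highest.

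Among cell cycle genes few passed. CCND1, which encodes cyclin D1 and drives entry into S phase, fell from 174 ± 20.6 to 124 ± 9.72 CPM (SD, n = 3; log2 fold change -0.48, adjusted p = 3.17e-06). It was the 1 of 25 G1/S genes to fall, and 3 fell adjusted over the list alone (camera adjusted p = 0.0438 with the group alone, 0.0878 with the table term; 0.610 and 0.707 with an estimated correlation). The call with the group alone ended in 5 of 6 fits with 1 library left out: without control replicate 2 (0.0737), knockdown replicate 1 (0.233) or 2 (0.0532), or the second table's control (0.428) or knockdown (0.0636) library. With the table term the G1/S list passed in camera without knockdown replicate 2 (adjusted p = 0.0311). Of 18 CDK inhibitor and pocket protein genes 2 rose, and 2 adjusted over the list alone: CDKN1C, encoding p57 (0.51), and CDKN1B, encoding p27 (0.25). The list did not pass in either fit (0.0795 and 0.0507). Of 24 G2/M genes 0 passed either way (0.302 and 0.138), and the proliferation markers TOP2A and MKI67 had 0.02 and -0.06. Of 25 p53 target genes 2 rose, TP53INP1 (0.31) and the antiproliferative BTG2 (0.24), and 3 adjusted over the list alone. Camera gave that list 0.198 with the group alone and 0.0204 with the table term (0.769 and 0.674 with an estimated correlation). The call ended without control replicate 1 (just above 0.05), knockdown replicate 1 (0.115), and the second table's control (0.118) or knockdown (0.113) library.

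Lists of genes that act with or beside UBE2A and UBE2B did not pass, apart from the proteasome. They were read under a partial fall of both transcripts, so they do not speak for a full loss. Of 32 ubiquitin E2 genes 1 fell, UBE2D1 (-0.32), and 4 adjusted over the list alone; neither target is in the list (camera adjusted p = 0.538 with the group alone and 0.491 with the table term). Of 20 genes of RAD18-dependent damage tolerance 0 passed either way (0.902 and 0.975), with -0.06 for USP1 and -0.05 for RFWD3. Of 17 genes of histone H2B ubiquitination 1 fell, the H2B deubiquitinase gene USP22 (-0.26), and 3 adjusted over the list alone (0.792 and 0.859). Of 15 N-degron pathway genes 0 passed either way (0.922 and 0.859), with -0.04 for HSPA5 and -0.03 for UBR4. Proteasome subunits had a median of -0.07 and 29 of 31 were negative; PSMD12 (-0.21) was the 1 that fell, and 4 fell adjusted over the list alone. Their camera adjusted p was 0.00182 and 0.00108, 0.610 and 0.707 with an estimated correlation, and with the table term 0.0530 or 0.0552 without the second table's control or knockdown library. The p with the group alone was 0.0802 without control replicate 2 and 0.119 without the second table's knockdown library, with a median of -0.05 in each. Without knockdown replicate 2 the median was -0.12 with the group alone and -0.11 with the table term.

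Replication-dependent histone genes had a median of 0.26 and 17 of 20 were positive, yet 0 passed singly over all genes or adjusted over the list alone. H2AC6 had 0.29 and H1-2 had 0.16, and reads of these near-identical copies are uncertain. Camera gave 0.00484 with the group alone and 0.00274 with the table term (0.610 and 0.542 with an estimated correlation). The p with the table term was 0.0665 without control replicate 1 and 0.0520 without the second table's knockdown library, and with the group alone 0.151 and 0.218. Without the second table's control or knockdown library the median was 0.42 or 0.16 with the group alone and 0.17 in both with the table term. Interferon-stimulated genes had a median of 0.18, with IFIT1 (0.47) the 1 of 20 to rise over all genes and 4 adjusted over the list alone. Their p was 0.0438 and 0.00613 (0.610 and 0.542 with an estimated correlation), and with the table term 0.0530 or 0.0552 without the second table's control or knockdown library. The interferon call with the group alone ended in 5 of 6 fits with 1 library left out: without control replicate 1 (0.133) or 2 (0.357), knockdown replicate 1 (0.0589), or the second table's control (0.0796) or knockdown (0.380) library. Their median there was 0.08 without control replicate 2, and 0.27 or 0.04 without the second table's control or knockdown library; with the table term it was 0.09 without either of these. Ribosomal protein genes had a median of 0.06 with 0 of 42 passing either way, RPS2 at 0.04 and RPL7A at 0.09. Their p was 0.0257 and 0.00959 (0.760 and 0.808 with an estimated correlation), and with the table term 0.940, 0.0575 and 0.172 without control replicate 1, knockdown replicate 1 and knockdown replicate 2. Those with the group alone were 0.798, 0.0580 and 0.110, and 0.111 without the second table's knockdown library. The ribosomal median with the group alone was -0.0027 without control replicate 1 and 0.11 without the second table's control library. In the fit with the table term it was 0.01 and 0.09 without control replicates 1 and 2, 0.03 without knockdown replicate 2, and 0.10 without either library of the second table.

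Of 23 ATF4 and unfolded protein response genes 1 fell, the cystine transporter gene SLC7A11 (-0.71), and 3 adjusted over the list alone (camera adjusted p = 0.989 with the group alone and 0.859 with the table term). Of 21 immediate early and NF-kB genes 1 fell, the phosphatase gene DUSP1 (-0.33), and 2 adjusted over the list alone (0.538 and 0.859). Of 13 mitochondrially encoded genes 0 passed either way (0.335 and 0.329), with 0.06 for MT-CO1 and 0.01 for MT-CO3. The camera direction differed in sign from the median or the mean with the table term for 5 lists: H2B ubiquitination, N-degron, ATF4, mechanosensors and damage tolerance.

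Some kidney tubule and neural or adrenal markers passed with the table term. Kidney tubule epithelial markers had 6 tested genes with 2 falling, and 2 adjusted over the list alone, the keratins KRT18 (-0.34) and KRT8 (-0.31), which overlap on chromosome 12 at 52948871 to 52949954 and cannot be separated without strand (camera adjusted p = 0.538 in both fits). Of 6 neural and adrenal markers SOX2 rose (0.39) and NEFL fell (-0.22), with 2 higher and 1 lower adjusted over the list alone (0.894 and 0.521). Of 8 fibroblast markers 0 passed either way (0.302 and 0.147), with -0.02 for FBLN1 and 0.01 for COL3A1. With the group alone the fibroblast list passed in camera without the second table's control library (adjusted p = 0.0452, median 0.26). With the table term the kidney list passed without knockdown replicate 1 (0.0207, median -0.25). Blood cell markers had 2 tested members, too few for a set test: CD34 had 1.44 CPM in the controls and a log2 change of -0.23 that did not pass.

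Short sequences in 3′ UTRs went with the lower genes. Of 247 lower genes with a searched 3′ UTR, 127 (51.4%) held the 7-mer ATGAATT, against 20.5% of the other genes and 17.2% of the higher ones. The 7-mer was picked as the lowest of 16213 from the same fold changes, so these shares carry no test, and they are not adjusted for 3′ UTR length. With length and GC content in the fit it also ranked lowest in the first table alone (z = -9.29), and in the second table, which had no part in that ranking, it ranked 2 from the bottom (z = -6.96). Among the lower named genes it was present in DDAH1, B4GALT6, LPCAT2, EMILIN2, CAV1, SLC7A11, CCND1, YAP1, USP22, UBE2D1, PSMD12 and NEFL. It was absent from ANKRD1, CCN2, TEAD4, INSIG1, KRT8, KRT18, FLNA, TAGLN2, ATG10, COL12A1, THBS1, ITGB1, SLC2A1, SLC2A3 and DUSP1. Of these, ANKRD1, ATG10, THBS1 and ITGB1 held another of the 4 7-mers that lay below the lowest permutation, in THBS1 the overlapping TGAATTA. ATGAATT was also present in the higher TRIM22 and ATP8A2, and in CTNNA1 (-0.05) and H2AC6 (0.29), which did not pass.

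Of 41 named genes past the threshold with the table term, targets left out, 6 stayed past it in each alternative with that term that tested them: DDAH1, B4GALT6, LPCAT2, CAV1, CCN2 and SLC7A11. The other 35 lost it in at least 1, and 0 turned in sign. Of the 6, all but CCN2 hold ATGAATT. The test on genes lacking the 7-mers left those out, so it could not end their calls. The controls had no siRNA, and neither the general response to siRNA nor cell density could be separated from the partial fall of UBE2A and UBE2B.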

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

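The test of a difference between the tables was chosen after the data were seen. The change of ITPRIPL2, a relative of a protein that binds the inositol trisphosphate receptor, differed between the tables by 0.89 on the log2 scale (edgeR interaction term, adjusted p = 0.0279, with 628 of 13629 genes at an unadjusted p under 0.05). The share of genes at that unadjusted p is below the 0.05 that p-values give where nothing differs. The log2 fold change of ITPRIPL2 was -0.16 in the first table and 0.73 in the second. In the second it stood at 36.6 CPM in the control and 60.8 CPM in the knockdown library. The second table's difference rests on 1 library per group, and no explanation was tested. Groups of 3 were too small for a check of libraries far from the others.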

How the results depend on the processing

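Alternatives that combine the table term with another choice, and the tests on genes with 1 model in both tables and on genes lacking the 7-mers, were chosen after seeing the data; the others were fixed before the data were examined. Where a value moved, the cause was not tested unless a cause is given. With the group alone, leaving out 1 library leaves the tables unequally shared between the groups. The difference between the tables then enters those fold changes. IFIT1 ran from -0.22 to 1.07 there, against 0.31 to 0.53 with the table term. FBLN1 ran from -0.23 to 0.21, against -0.025 to -0.0061. The alternatives on pseudocounts and low normalized values were not run, since counts were given. UBE2A kept its direction in each alternative, at -0.85 where it was smallest. With the group alone its call was gained with no filter (-0.93, adjusted p = 0.0320), DESeq2 (-0.93), the table term (-0.93) and the first table (-0.85). UBE2B gained its call with the table term (-0.30) and lost it against a 1.2-fold minimum (-0.30). Calls with the group alone numbered 0 with RLE factors, limma-voom, the 5 CPM minimum, the 1.2-fold minimum and each library left out, 1 with no filter, 2 with DESeq2, 336 with the table term and 154 in the first table alone. The table term lowered the biological coefficient of variation from 14.4% to 5.44%. With the table term 336 (87 higher, 249 lower) became 204 with DESeq2 (25 and 179; 195 shared), 16 against a 1.2-fold minimum (0 and 16) and 127 among genes lacking the 7-mers (48 and 79). The last setting tests fewer genes, and the lower calls shrank more than the higher ones. The 7-mers were picked for going with lower values in these same data, so that difference carries no test. Other choices gave 307 to 432.

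Leaving out 1 library moved the count with the table term between 98 and 420, and UBE2B between -0.35 and -0.25; without a library of the second table, the other carries no information on the groups. The number of lists past the threshold lay between 3 and 9 with the group alone and 5 and 9 with the table term. Cholesterol synthesis passed in each of these fits. YAP/TEAD targets and hypoxia and glycolysis genes passed in each of those with the table term, and not in each with the group alone. With an estimated correlation 0 lists passed in either fit, and with fry 0 and 0; fry asks whether a list's genes move one way and compares them with no other genes.

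The replicate block gave 363 calls, 335 of them shared with the table term, UBE2A at -0.93 and UBE2B at -0.30. The numbers cover 2 pairs, and the unnumbered libraries formed the remaining block by their shared table. Deviations from group means correlated at 0.30 and 0.39 for libraries with the same number, 0.34 and 0.34 across numbers, and 0.68 for the unnumbered pair. The difference between the tables is part of these deviations, so they cannot tell whether samples were paired. Within the first table, the difference between knockdown replicates 1 and 2 correlated at 0.012 across genes with that between control replicates 1 and 2. That value gives no sign of pairing by number. Under the block the camera direction turned for ATF4 and mechanosensor genes (adjusted p = 0.872 each) and neural markers (0.551).

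Lists that turned in direction did not pass in either setting, except where said. Against the group alone these were N-degron with fry (0.996), ATF4 and mechanosensors with no filter (0.973 each) and with the table term (0.859 each), neural markers with the table term (0.521), and mechanosensors (0.755) and neural markers (0.436) in the first table. With the table term these were damage tolerance with no filter (0.981) and 1 gene model (0.727), immediate early genes at 5 CPM (0.862), ATF4 with 1 gene model (0.963), and H2B ubiquitination and mechanosensors without the 7-mers (0.799 each).

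Leaving out 1 library with the group alone, adjusted p of lists that turned lay between 0.128 and 0.897 for ATF4, 0.0652 and 0.687 for G2/M, 0.151 and 0.978 for immediate early, 0.480 and 0.832 for mechanosensors, 0.0464 and 0.975 for mitochondrial genes, 0.266 and 0.966 for N-degron, 0.312 and 0.996 for neural markers, 0.0168 and 0.736 for p53 targets, 0.244 and 0.978 for damage tolerance, and 6.14e-04 and 0.798 for ribosomal proteins, which passed with all libraries. With the table term they lay between 0.156 and 0.949 for ATF4, 0.436 and 0.915 for immediate early, 0.589 and 0.881 for mechanosensors, 0.440 and 0.881 for N-degron, 0.125 and 0.956 for neural markers, and 0.817 and 0.940 for damage tolerance.

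The genes that turned were uncalled with the group alone. HSPA5 was at 0.0064 in the first table alone. Leaving out 1 library gave log2 fold changes from -0.47 to 0.036 for CD34, -0.012 to 0.056 for CTNNB1, -0.039 to 0.14 for TOP2A, -0.16 to 0.023 for MKI67, -0.23 to 0.21 for FBLN1, -0.049 to 0.074 for COL3A1, -0.22 to 1.07 for IFIT1, -0.19 to 0.017 for LMNB2, -0.015 to 0.028 for MT-CO3, -0.26 to 0.16 for HSPA5, -0.21 to 0.077 for UBR4, -0.017 to 0.56 for BTG2, -0.15 to 0.44 for H1-2, -0.098 to 0.18 for RPS2 and -0.016 to 0.24 for RPL7A. With the table term, among uncalled genes, these were -0.49 to 0.034 for CD34, -0.0050 to 0.084 for TOP2A, -0.012 to 0.023 for COL3A1, -0.016 to 0.045 for MT-CO3 and -0.17 to 0.055 for HSPA5. Depth limits the rarest of these: CD34 lay near 1.44 CPM in the controls, above the floor of 0.276 CPM.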

Other observations

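The Gene Ontology terms, the 4 7-mers as a set, the site types, the base composition and the splits with the group alone were tests chosen after the result was seen; the splits with the table term, the leading 7-mer and the GC and length tests were set out before their results. Among 517 biological process terms of 15 to 300 tested genes, as the deposited first table assigns them, 2 passed in camera with the preset correlation and the table term, both lower, and 0 with an estimated correlation (adjusted p = 0.995 for both). Ribosome biogenesis (69 genes, median log2 fold change -0.09, adjusted p = 1.74e-05) held 4 genes that fell over all genes, EBNA1BP2, HEATR1, IMP4 and WDR43. Processing of rRNA (122 genes, median -0.07, adjusted p = 0.00123) held 10, with DDX21 (-0.25), NOL6 (-0.29) and UTP20 (-0.23) among the further ones. All these genes were chosen after their values were seen.

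With the table term the real grouping gave 336 calls, and the highest of the other 9 of the 10 splits of the 6 libraries into 3 and 3 gave 1, so 1 of 10 splits gave as many. With the group alone the real grouping and each other split gave 0 calls, so all 10 were alike. The splits are too few for a share under 0.05. In some of the other splits both libraries of the second table fell in 1 group, unlike in the real grouping. Each other split also mixes knockdown and control libraries, so a knockdown effect would add to its spread. The counts therefore do not measure chance.

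The lower genes were rich in a 7-mer of their 3′ UTRs, ATGAATT, with a z of -10.2 against a lowest z of -5.01 in 100 permutations. The next, TGAATTA (-9.05), overlaps it by a base shift, and both ranked first or second from the bottom in each table separately. Genes with the 8-mer ATGAATTA had a median log2 fold change of -0.0457 (95% interval -0.0552 to -0.0363, 712 genes), those with ATGAATT alone -0.0264 (-0.0327 to -0.0207) and those with no match 0.0069, while the 129 other 7-mers of the same bases that share no run of 5 bases with ATGAATT reached a z of -3.76 at lowest, which argues against base composition. Those left out share such a run, TGAATTA (-9.05) and GAATTAT (-4.99) among them. A candidate explanation for part of the calls is seed matching by a transfected siRNA, since the 7-mer occurs in 5 of 11 UBE2A and 1 of 8 UBE2B transcripts, although 35.8% of all 7-mers occur in 1 or the other. The 8-mer ATGAATTA lies in the longest annotated 3′ UTR of both genes. A part of such matching in their own falls, the small one of UBE2B included, could not be separated here. The siRNA sequences were not analysed here, so a microRNA with that seed stays open, and the partial fall of UBE2A and UBE2B stays a candidate cause too. Of 247 lower genes, 127 held ATGAATT and 176 (71.3%) at least 1 of the 4 7-mers below the lowest permutation, as did 42.9% of all searched genes and 42.5% of the higher ones. The other 71 lower genes held none of the 4. Since the 4 were picked on the same fold changes, these shares carry no test.

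YAP/TEAD targets were also lower among members whose searched 3′ UTR lacked these 7-mers, so those matches do not account for these members. Matches to other sequences, or outside the longest annotated 3′ UTR, were not tested. The 5 members with ATGAATT had a median log2 fold change of -0.05. The 16 members without ATGAATT had a median of -0.23 (95% bootstrap interval -0.44 to -0.11), the 12 with none of the 4 7-mers -0.16 (-0.27 to -0.08), and removal of a GC content and length trend left -0.18 (-0.36 to -0.07). An indirect path through YAP1, whose 3′ UTR holds 2 copies of the 8-mer, was not tested and may account for part. Cell density and a general response to siRNA cannot be separated from the knockdown in this design. A change in YAP/TEAD output on the partial fall of UBE2A and UBE2B stays a hypothesis.

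Cholesterol synthesis genes were likewise lower among members whose searched 3′ UTR lacked these 7-mers, with the same limit on other matches. The 3 members with ATGAATT had a median log2 fold change of -0.42. The 16 members without ATGAATT had a median of -0.24 (-0.39 to -0.13), the 13 with none of the 4 7-mers -0.24 (-0.39 to -0.13), and removal of the GC and length trend left -0.26 (-0.39 to -0.15). These intervals, like those of the YAP/TEAD targets, draw list members as if they were independent genes. An indirect path through other genes that hold such matches was not tested. The protocol text, alike for both groups, gives the lipid reagent with or without siRNA, while the labels of the controls say only vehicle. An effect of lipid uptake thus stays open as a candidate cause. So do density, a general response to siRNA, an indirect effect of seed matches in other genes, and the knockdown itself. Among genes whose 3′ UTR lacks the 4 7-mers, camera with the preset correlation gave adjusted p of 1.76e-08 for this list and 0.00413 for YAP/TEAD targets; over all genes neither list passed with an estimated correlation (0.674 each with the table term).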
